A study of Rattus norvegicus with 10 samples.

How the data were processed

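Gene expression was measured on 10 Affymetrix rat expression arrays, each hybridised with biotin-labelled total RNA from microglia, the resident macrophages of the brain. Per the labels, the cells came from neonatal rat brain and were grown in medium with 15% fetal calf serum, changed on days 7 and 11. They were plated at 100000 cells per dish on day 15. The control dishes received fresh medium. The other dishes received fresh medium with 100 U/ml interferon gamma (IFN-gamma), a cytokine released by T cells and natural killer cells, for 16 hours. The 5 control arrays came from 5 independent cultures (numbered 1, 2, 3, 5 and 6). The 5 IFN-gamma arrays came from 3 cultures, of which culture 1 was run as 3 technical arrays (1a, 1b and 1c). The culture was taken as the replicate, so the 3 technical arrays were averaged on the log2 scale and the comparison rested on 5 control and 3 IFN-gamma cultures.

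The deposited table holds 1 signal intensity per probe set and array on a linear scale. The submitters' processing notes name MAS5 and GCRMA with no version and no role for either, so which of them made the deposited intensities is not given in the sources used here. The deposited intensities were not on a common scale, since the median signal of an array ran from 7.4 (control culture 3) to 23.7 (IFN-gamma array 1b). No pair of arrays shared the same deposited signal at more than 81 probe sets, so no array was taken as a duplicate of another. The number of arrays limits the precision of every value.

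Of the 8799 probe sets in the table, 59 were array controls and were left out of the tests, which covered 8740. Gene symbols came from the platform annotation supplied with the table, checked through Entrez identifiers against a RefSeq gene table of the rat assembly GRCr8. Of the tested probe sets 7006 had 1 symbol, 308 had several and 1426 were not listed with a gene. An Entrez identifier was found in the RefSeq table for 6985 of them, and 0 symbols needed an update. Probe sets with several symbols are not named as genes. The build behind the array design is not given in the sources used here, so no coordinates are printed. A gene with several probe sets was represented by the one with the highest mean over the 8 cultures, which gave 4736 genes, and the text names each list member that passed only by another probe set and each named gene past the threshold with a probe set of the opposite sign. Class I genes of the rat major histocompatibility complex (RT1) are near-identical copies, so a probe set named for such a gene may also bind transcripts of its neighbours.

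From these intensities log2(signal + 16) was computed, the 10 arrays were quantile normalised on that scale and the technical arrays were averaged. A signal of 0 is 4 on this scale and the smallest normalised value was 4.02, so log2 fold changes understate the change of dim genes. The tests, gene lists, named genes and most alternatives were set before the data were examined, with the table's own scaling as the first choice. Because the table was not on a common scale, quantile normalisation, until then an alternative, was made the main setting after the values were seen. The unscaled values became an alternative. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term, two-sided), with Benjamini-Hochberg adjustment over 8740 probe sets and a threshold of 0.05. Every adjusted p of a gene comes from that test.

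In all 29 gene lists were fixed, 23 of pathways or complexes and 6 of cell type markers. Each list was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 23 lists and over the 6 lists separately, and again with a correlation estimated for each list (statmod 1.5.0). The test fry, which asks whether the genes of a list move on balance one way and does not compare them with other genes, was run beside it. The count of members past the threshold is given over all probe sets tested and adjusted over the list alone. Genes were named by a fixed rule. It took the 12 largest increases and the 12 largest decreases among genes past the threshold whose 3 IFN-gamma cultures all lay outside the range of the controls. It added up to 4 members with the smallest adjusted p from each list, and a fixed set of interferon, inflammatory and cell type genes whether they passed or not. Exceptions are marked as named after their values were seen. Single values per culture were compared with an exact two-sided permutation test over the 56 splits of 8 cultures into 3 and 5, for which the smallest p is 0.018. Because culture numbers 1, 2 and 3 occur in both groups and the labels do not say that a number marks a shared brain or day, the fit has no block.

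The limma step was checked on simulated data whose spread was taken from the real fit. In these, 200 of 8740 probe sets were changed in the IFN-gamma against control comparison. All 200 had a mean level above the median of the probe sets, so recovery of dimmer ones was not measured. The step recovered 21% of 100 probe sets set to a log2 change of 1 and 80% of 100 set to a log2 change of 2. The median estimated change of these was 0.97 and 1.73, and 4 unchanged probe sets were called (3.81% of the calls). Other settings tried were each technical array alone, all 10 arrays with culture as a random block, array medians subtracted and filters on dim probe sets. Further ones were other variance and weighting options, a replicate block, another offset or floor, each culture left out in turn, stricter thresholds and other rules for probe sets. Settings added after the values were seen were the unscaled table, scaling of each array to a mean of 500 with 2% trimmed at each end, and array brightness as a covariate. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.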

Results

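The series asked how cultured neonatal rat microglia respond to activation by IFN-gamma. It holds 10 arrays: 5 from unstimulated control cultures and 5 from 3 cultures exposed to 100 U/ml IFN-gamma for 16 hours, with IFN-gamma culture 1 measured on 3 arrays. The median deposited signal per culture was 15.3 ± 5.5 (SD, n = 5) in the controls and 17.5 ± 3.21 (SD, n = 3) with IFN-gamma, a difference within the spread between cultures (exact permutation p = 0.554, two-sided). The ratios of 3' to 5' signal of the GAPDH and beta-actin array controls, a sign of RNA integrity, did not differ either (exact permutation p = 0.214 and 0.518, two-sided). The dimmest array was control culture 3, with a median of 7.4 and 29.1% of probe sets above a signal of 16, against 41% to 55.6% in the other controls. Levels below are normalised log2(signal + 16) values and fold changes are on that scale, so a control level near 4 lies at the floor and its fold change is understated.

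IFN-gamma raised genes of antigen presentation far above the control level. It lowered other genes, among them Pf4, the cathepsin genes Ctsl and Ctsd, the lipoprotein lipase gene Lpl and the matrix genes Spp1 and Fn1. The largest increase was in Cd74, the invariant chain that chaperones class II molecules, which rose 47.9-fold from 4.51 ± 0.41 (SD, n = 5) to 10.1 ± 0.175 (SD, n = 3; adjusted p = 5.51e-06). The largest decrease was in Pf4, the chemokine CXCL4, which fell 12.2-fold from 9.77 ± 0.221 to 6.15 ± 0.103 (adjusted p = 8.06e-06). In all, 81 of 8740 probe sets were higher and 53 lower with IFN-gamma at an adjusted p under 0.05, 75 and 44 of them by at least 2-fold. In each of these 134 probe sets the 3 IFN-gamma cultures lay entirely above or entirely below the 5 controls. Such separation was seen in 374 probe sets above and 297 below, where chance gives 156 per direction (1.79%). Counted as genes by the brightest probe set, 42 were higher and 33 lower, and 22 of the called probe sets had no single symbol. The balance of directions depended on the scaling. Higher calls were 60.4% of all calls here, 78.7% (100 higher, 27 lower) with array medians subtracted and 97.4% (38 higher, 1 lower) with no scaling between arrays. With no scaling all of the 12 largest decreases, Pf4 included (adjusted p = 0.0677), kept their direction but lost their call.

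**Figure D1:**
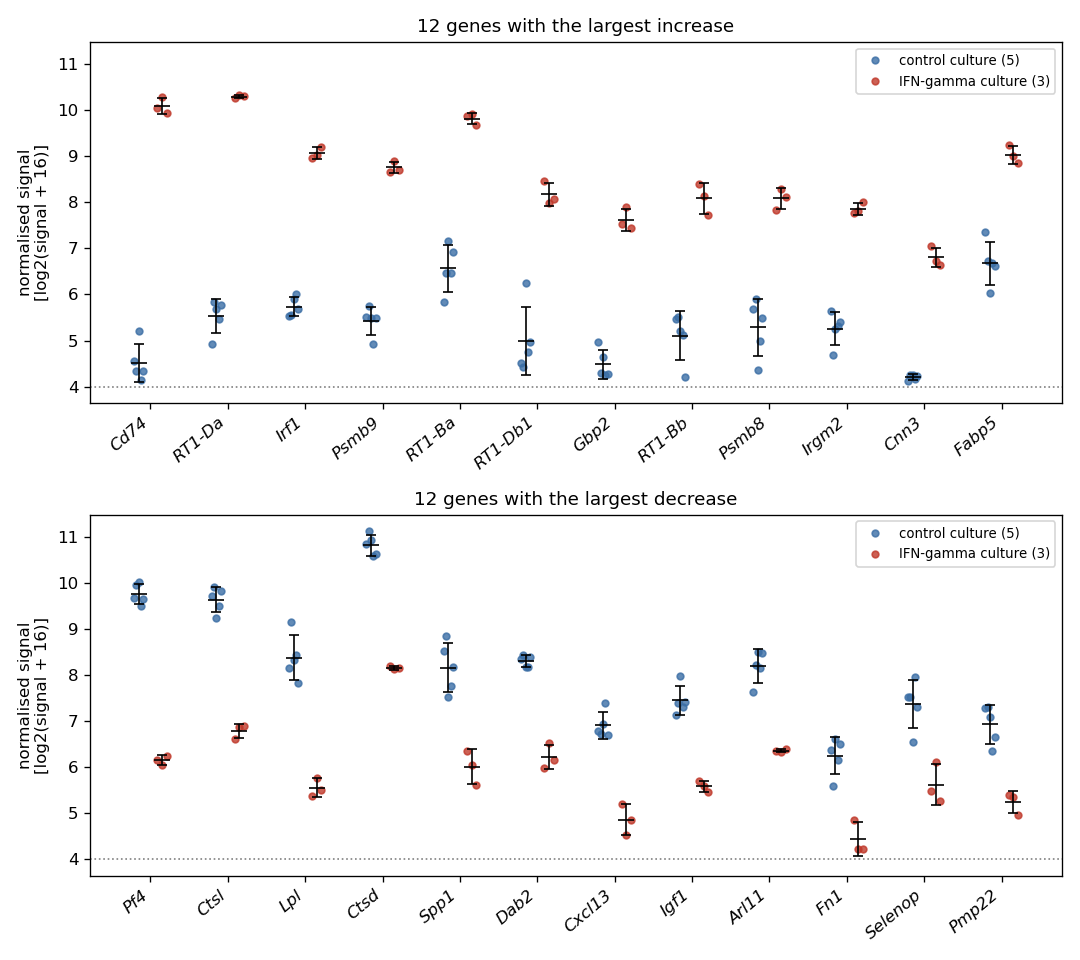
Normalised signal, log2(signal + 16), of the 12 genes with the largest increase (top) and the 12 with the largest decrease (bottom). Each point is 1 culture (5 control, 3 IFN-gamma), the horizontal black bar is the group mean and the whiskers 1 SD, and the dotted line marks a signal of 0 (4 on this scale); Cd74 averaged 4.51 in the controls and 10.1 with IFN-gamma, and Pf4 averaged 9.77 and 6.15.

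Class II antigen presentation showed the largest change of any pathway list apart from the smaller immunoproteasome list. Of 11 measured genes 5 rose and 0 fell (8 rose adjusted over the list alone), with a median log2 fold change of 1.84 (camera adjusted p = 1.19e-16, 0.00227 with an estimated correlation). Besides Cd74 these were genes of class II chains. RT1-Da rose 27.2-fold to 10.3 ± 0.038 (SD, n = 3; adjusted p = 6.95e-06). The others were RT1-Ba (9.5-fold, adjusted p = 0.000374), RT1-Db1 (9.12-fold, adjusted p = 0.00299) and RT1-Bb (7.91-fold, adjusted p = 0.00116). All other probe sets of Cd74, RT1-Da, RT1-Ba and RT1-Db1 had a log2 fold change of the same sign. RT1-Bb had 4 others, of which 3 did and 1 dim probe set lay at -0.08. RT1-DMb, named after its values were seen, did not pass by its brightest probe set (log2 fold change 1.84, adjusted p = 0.141), but 2 others rose by 2.62 (adjusted p = 0.0121) and 1.97 (adjusted p = 0.021).

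Class I antigen presentation rose as well. Of 12 measured genes 5 were higher and 0 lower (10 higher and 1 lower adjusted over the list alone), with a median log2 fold change of 0.96 (camera adjusted p = 8.84e-12, 0.0131 with an estimated correlation). Tap1, which carries peptides into the endoplasmic reticulum, rose 5.06-fold (log2 fold change 2.34 ± 0.288 SE, adjusted p = 0.00301). B2m, the light chain of class I molecules, was already at 9.34 ± 0.2 in the controls (SD, n = 5) and rose 3.09-fold (adjusted p = 0.0017, call lost in 4 of 23 other settings). The class I heavy chain genes RT1-CE12 and RT1-S3 rose 3.59-fold (adjusted p = 0.000374) and 3.47-fold (adjusted p = 0.0239). The call of RT1-S3 was lost in 11 of 23 other settings. RT1-CE16, named after its values were seen, was the remaining member (log2 fold change 1.26, adjusted p = 0.0326).

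All 4 measured genes of the immunoproteasome and its PA28 activator, which generate peptides for class I molecules, rose (4 adjusted over the list alone). The median log2 fold change was 2.26 (camera adjusted p = 3.3e-12, 0.00719 with an estimated correlation). The catalytic subunits Psmb9 and Psmb8 rose 10.1-fold (adjusted p = 3.06e-05) and 6.97-fold (adjusted p = 0.00268), and the activator subunits Psme2 and Psme1 rose 3.31-fold (adjusted p = 0.000374) and 2-fold (adjusted p = 0.0287). For Psme1 another probe set lay at -0.10 and the call was lost in 11 of 23 other settings. In the constitutive proteasome 1 of 22 measured genes rose over all probe sets tested, and 11 adjusted over the list alone. The median log2 fold change was 0.60 (camera adjusted p = 6.21e-09, but adjusted p = 0.141 with an estimated correlation; fry adjusted p = 0.0349). That gene was the core subunit gene Psma5 (2.27-fold, adjusted p = 0.0453), whose call was lost in 12 of 23 other settings. Psma4 and Psmb4 had log2 fold changes of 0.77 and 0.83 and did not pass (adjusted p = 0.0838 and 0.115). Psma2 had 1.17 by its brightest probe set (adjusted p = 0.106) and 1.36 by another that passed (adjusted p = 0.0459).

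Among 23 genes of JAK-STAT and IRF signalling, the pathway that carries the interferon signal to the nucleus, 3 rose and 0 fell (6 rose adjusted over the list alone). The list was higher by camera (adjusted p = 0.0015, but adjusted p = 0.0607 with an estimated correlation). The transcription factor gene Irf1 rose 10.1-fold from 5.74 ± 0.21 (SD, n = 5) to 9.07 ± 0.124 (SD, n = 3; adjusted p = 1.08e-05) and Irf8 rose 2.85-fold (adjusted p = 0.00112). Cish, a feedback inhibitor of cytokine receptors, rose 1.88-fold (adjusted p = 0.037), with the call lost in 16 of 22 other settings. Irf7 had a log2 fold change of 1.57 and did not pass (adjusted p = 0.237), and neither did the receptor gene Ifngr1 (-0.28, adjusted p = 0.648). Of 11 interferon-induced GTPases and antiviral genes 3 rose and 0 fell (4 rose adjusted over the list alone; camera adjusted p = 1.91e-06, 0.0147 with an estimated correlation). The guanylate-binding protein gene Gbp2 rose 8.77-fold (adjusted p = 8.76e-05), the immunity-related GTPase gene Irgm2 6.08-fold (adjusted p = 0.00036) and the antiviral Mx1 4.36-fold (adjusted p = 0.0226), with the call of Mx1 lost in 10 of 23 other settings, among them without IFN-gamma culture 1, 2 or 3 and without control culture 2 or 6.

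Chemokine genes moved in both directions. Of 22 measured chemokine and receptor genes 1 rose and 3 fell (1 and 4 adjusted over the list alone). Cxcl10, which attracts activated T cells, rose 4.29-fold (adjusted p = 0.00176), while Pf4, the B cell chemokine gene Cxcl13 (4.14-fold lower, adjusted p = 0.0017) and the monocyte chemokine gene Ccl2 (2.79-fold lower, adjusted p = 0.0473) fell. The call of Ccl2 was lost in 16 of 23 other settings. Ccl5 stayed near the floor, at 4.30 ± 0.0719 in the controls (SD, n = 5) and 4.34 ± 0.0727 with IFN-gamma (SD, n = 3; adjusted p = 0.978). The list as a whole was lower by camera (median log2 fold change -0.04, adjusted p = 0.0359, but adjusted p = 0.161 with an estimated correlation). That call was lost in 8 of 26 other settings, among them without control culture 1 (adjusted p = 0.0854), control culture 2 (0.084), control culture 6 (0.0612) or IFN-gamma culture 2 (0.0978), and the median was 0.01 with no scaling between arrays.

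Of 26 measured inflammatory cytokine genes 0 rose and 1 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.234), the 1 being Il1a (1.89-fold lower, adjusted p = 0.0473), whose call was lost in 19 of 23 other settings. Il1b, at 9.30 ± 0.242 in the controls (SD, n = 5), had a log2 fold change of -0.82 (adjusted p = 0.0724). Nos2, the inducible nitric oxide synthase gene, had a log2 fold change of 0.47 ± 0.382 SE (adjusted p = 0.798), and Tnf, Il6 and Il18 had 0.16 (adjusted p = 0.889), 0.51 (adjusted p = 0.423) and -0.12 (adjusted p = 0.964). Tnf and Il6 lay near the floor, at 4.57 and 4.31 in the controls, which leaves little room for a fall to be seen.

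In the complement list 3 of 14 genes rose and 0 fell (3 and 1 adjusted over the list alone). Serping1, the C1 inhibitor gene, rose 3.75-fold (adjusted p = 0.00557), and C1qc and C1qb, which encode chains of C1q, rose 2.48-fold (adjusted p = 0.0364) and 2.21-fold (adjusted p = 0.0239), with calls lost in 12 and 10 of 23 other settings. C3 did not pass (log2 fold change 0.67, adjusted p = 0.338). The list did not pass by camera (adjusted p = 0.0515), although it was higher in 11 of 26 other settings. These included array medians subtracted (adjusted p = 0.00287), no scaling (0.00867), the trimmed mean (0.0208), array 1a alone for IFN-gamma culture 1 (0.0267) and the omission of control culture 2 (0.0463), control culture 3 (0.0436) or IFN-gamma culture 2 (0.0499). With an estimated correlation it did not pass (adjusted p = 0.135). By fry, which does not compare the genes with other genes, it passed (fry adjusted p = 0.000122). Of 18 genes for Fc receptors, adhesion and costimulation 1 rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.0855, past the threshold in 3 of 26 other settings). The costimulatory receptor gene Cd40 rose 2.81-fold from a control level of 4.27 (adjusted p = 0.00301) and Fcgrt, the neonatal Fc receptor gene, was 2.52-fold lower (adjusted p = 0.0177, call lost in 8 of 23 other settings, among them no scaling, array medians, the trimmed mean and the omission of IFN-gamma culture 1, 2 or 3). Icam1 had a log2 fold change of 1.35 by its brightest probe set (adjusted p = 0.0819) and 1.13 by another that passed (adjusted p = 0.0459). The list of Fc receptors, adhesion and costimulation also passed by fry (fry adjusted p = 0.0349).

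Of 24 measured lysosome and cathepsin genes 0 rose and 5 fell (5 adjusted over the list alone). The protease genes Ctsl and Ctsd were 7.19-fold lower (adjusted p = 7.41e-05) and 6.35-fold lower (adjusted p = 5.17e-05), and Lamp1, Cd63 and Ctsb (the last named after its values were seen) were 2.38-fold, 2.12-fold and 2.36-fold lower (adjusted p = 0.0043, 0.0074 and 0.021). The calls of Ctsl and Ctsd were each lost in 1 of 23 other settings, that with no scaling (adjusted p = 0.392 and 0.421). The call of Lamp1 was lost in 5 of 23 other settings and that of Cd63 in 6. Under no scaling, array medians and the trimmed mean the log2 fold change of Lamp1 was -0.542, -0.665 and -1.01 and that of Cd63 -0.265, -0.387 and -0.72, and neither passed. Without IFN-gamma culture 1 the adjusted p of Cd63 was 0.0633. Psap, a saposin precursor gene named after its values were seen, had a log2 fold change of 0.32 by its brightest probe set (adjusted p = 0.637), while 2 others rose by 1.19 (adjusted p = 0.00375) and 1.10 (adjusted p = 0.0171). The list as a whole was lower by camera (median log2 fold change -0.22, adjusted p = 4.6e-05, 0.0213 with an estimated correlation). That call was lost with array medians subtracted (median 0.11, adjusted p = 0.47), with no scaling (median 0.23, adjusted p = 0.31), with scaling to a trimmed mean (median -0.12, adjusted p = 0.146) and without probe sets of reduced specificity (median -0.08, adjusted p = 0.0539).

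Genes of extracellular proteases, inhibitors and matrix fell in 4 of 26 measured cases and rose in 0 (6 fell adjusted over the list alone; median log2 fold change -0.38, camera adjusted p = 4.85e-05, 0.0213 with an estimated correlation). They were the osteopontin gene Spp1 (4.46-fold lower, adjusted p = 0.00921), the fibronectin gene Fn1 (3.51-fold lower, adjusted p = 0.00921), the plasminogen activator gene Plau (2.49-fold lower, adjusted p = 0.013, call lost in 7 of 23 other settings) and the metalloproteinase inhibitor gene Timp2 (2.39-fold lower, adjusted p = 0.00568). The calls of Spp1, Fn1 and Timp2 were each lost in 5 of 23 other settings. Under no scaling, array medians and the trimmed mean Timp2 had log2 fold changes of -0.654, -0.777 and -1.13 and Plau had -0.977, -1.10 and -1.58, and neither passed. Without IFN-gamma culture 2 or 3 the adjusted p was 0.0558 or 0.0704 for Spp1 and 0.0651 or 0.0707 for Fn1, and without culture 1 or 3 it was 0.0818 or 0.0704 for Plau. The 4 other Fn1 probe sets were dim, with log2 fold changes between -0.19 and 0.08. Among 26 growth and neurotrophic factors 1 fell and 0 rose (1 adjusted over the list alone; median -0.35, camera adjusted p = 0.00169, adjusted p = 0.0607 with an estimated correlation). Igf1, insulin-like growth factor 1, was 3.64-fold lower (adjusted p = 0.00176), although 1 of its 4 other probe sets lay at 0.19.

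Lipid handling genes split. Of 32 measured genes 1 rose and 2 fell (1 and 3 adjusted over the list alone). The median of 0.11, the mean of -0.06 and the camera direction (down, adjusted p = 0.83) differed in sign. The fatty acid binding protein gene Fabp5 rose 5.12-fold (adjusted p = 0.00215), the lipoprotein lipase gene Lpl was 7.11-fold lower (adjusted p = 0.000935). Apoe, at 13.1 ± 0.103 in the controls (SD, n = 5), was 2.06-fold lower (adjusted p = 0.0167). The call of Apoe was lost in 8 of 23 other settings, among them no scaling, array medians, the trimmed mean and the omission of any IFN-gamma culture. The lipoprotein receptor gene Scarb1 had a log2 fold change of -1.48 by its brightest probe set (adjusted p = 0.116), and both others fell, by 2.29 (adjusted p = 0.0017) and 1.31 (adjusted p = 0.013). The remaining genes of the 12 largest decreases stood in no list. They were the endocytic adaptor gene Dab2 (4.26-fold lower, adjusted p = 0.000315), the small GTPase gene Arl11 (3.58-fold lower, adjusted p = 0.00268), the selenium transport gene Selenop (3.37-fold lower, adjusted p = 0.0287, call lost in 12 of 23 other settings) and Pmp22 (3.23-fold lower, adjusted p = 0.011, call lost in 5 of 23 other settings). Without IFN-gamma culture 1, 2 or 3 the adjusted p of Pmp22 was 0.0502, 0.0523 or 0.0806. Among the 12 largest increases Cnn3, a calponin gene, was the only one outside the lists (6.07-fold, adjusted p = 3.02e-05), and its other probe set, at 4.44 in the controls, lay at -0.09.

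In glycolysis 0 of 20 measured genes passed over all probe sets and 1 rose adjusted over the list alone. The list was higher by camera (median log2 fold change 0.38, adjusted p = 0.00402, adjusted p = 0.0503 with an estimated correlation). The glucose transporter gene Slc2a1 had a log2 fold change of 1.59 (adjusted p = 0.0501) by its brightest probe set and 1.60 by another that passed (adjusted p = 0.0373). Pgk1, named after its values were seen, had 0.61 by its brightest probe set (adjusted p = 0.691) and 0.88 by a dim one that passed (adjusted p = 0.037). The GAPDH array control for the 3' end, outside the tested probe sets, was at 9.63 ± 0.201 in the controls (SD, n = 5) and 10.6 ± 0.295 with IFN-gamma (SD, n = 3; exact permutation p = 0.0179, the smallest the design allows, adjusted p = 0.0716). The beta-actin control for the 3' end parted the groups as fully, at 11.1 ± 0.23 and 11.7 ± 0.0555 (SD; exact permutation p = 0.0179, adjusted p = 0.0716), so the separation was not particular to GAPDH. Of 29 oxidative phosphorylation genes 0 passed, and 0 adjusted over the list alone. The list was higher by camera (median 0.26, adjusted p = 0.000477), but not with an estimated correlation (adjusted p = 0.25; fry adjusted p = 0.166). Atp5f1b, with the smallest adjusted p of the list, had a log2 fold change of 1.01 (adjusted p = 0.0974). Of 37 ribosomal protein genes 0 passed, and 1 was lower adjusted over the list alone. The list was lower by camera (median -0.29, adjusted p = 0.000123), but not with an estimated correlation (adjusted p = 0.273) nor without IFN-gamma culture 1 (adjusted p = 0.0657). Their direction turned with the scaling, to a median of 0.25 with array medians subtracted and 0.38 with no scaling. Of 31 cell cycle genes 0 passed by their brightest probe set, and 0 adjusted over the list alone. Mcm6, named after its values were seen, had -0.47 by that probe set (adjusted p = 0.49) and -0.97 by another that passed (adjusted p = 0.0455). The list was lower by camera (median -0.15, adjusted p = 0.0392), but the call was lost in 11 of 26 other settings. Among these were an estimated correlation (adjusted p = 0.0968), array medians subtracted (0.0629), the trimmed mean (0.0527), all 10 arrays (0.0929) and the omission of control culture 1 (0.108), control culture 6 (0.0739) or IFN-gamma culture 1 (0.0799).

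The other pathway lists did not pass by camera. In oxidative burst and redox genes 0 of 20 rose and 1 fell (2 and 4 adjusted over the list alone; adjusted p = 0.851; the median of -0.002 and the mean of 0.04 differed in sign). That gene was Gpx3 (1.9-fold lower, adjusted p = 0.0446), with the call lost in 17 of 23 other settings. Prdx2 (log2 fold change 1.24, adjusted p = 0.0501) and Sod2 (0.07, adjusted p = 0.992) did not pass. The Sod2 value rests on control culture 1, at 9.21, against 6.32 to 6.67 in the other controls and 6.67 to 7.54 with IFN-gamma. Sod2 passed in none of the other settings (lowest adjusted p = 0.281). None of 12 apoptosis genes (camera adjusted p = 0.282), 16 cholesterol genes (0.63; median 0.01, mean -0.07), 17 arginine and tryptophan genes (0.233) or 28 stress and immediate early genes (0.851; median 0.04, mean -0.003) passed, with 0 in each adjusted over the list alone. As a list the arginine and tryptophan genes passed by fry (fry adjusted p = 0.0255), which does not compare them with other genes. Gch1, which makes a cofactor of nitric oxide synthase, had a log2 fold change of 0.67 (adjusted p = 0.383).

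**Figure D2:**
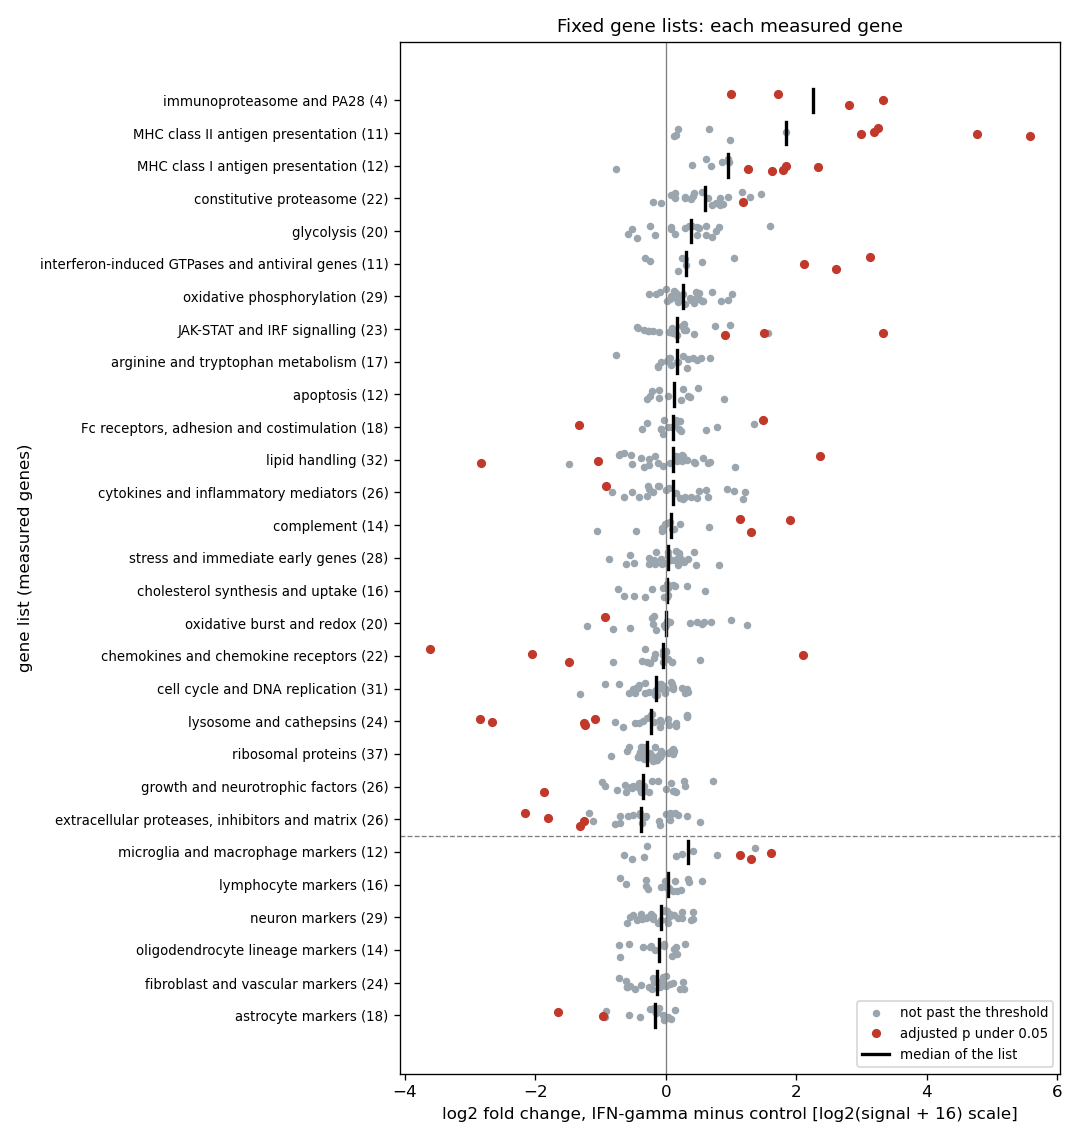
Log2 fold change, IFN-gamma minus control on the log2(signal + 16) scale, of each measured gene in the 29 fixed lists; marker lists stand below the dashed line and the number of measured genes follows each name. Red points passed an adjusted p of 0.05, grey points did not, and black bars are list medians, which ran from 2.26 for the immunoproteasome list to -0.38 for the protease and matrix list; the ribosomal median turned to 0.25 and 0.38, and the lysosomal median to 0.11 and 0.23, with array medians subtracted and with no scaling.

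Markers of cell types were compared in the same cultures. Of 12 measured microglia and macrophage markers 3 rose and 0 fell (5 adjusted over the list alone). The list was higher by camera (median log2 fold change 0.34, adjusted p = 0.00727, but adjusted p = 0.111 with an estimated correlation). Lyz2, the lysozyme gene, rose 3.05-fold from 10.8 ± 0.316 (SD, n = 5; adjusted p = 0.00464), with the call lost in 4 of 23 other settings. The others were C1qb and C1qc, and 4 of the 12 markers stand in another list too. Aif1, Csf1r and Cx3cr1 did not pass (log2 fold changes 0.42, 0.15 and -0.29, adjusted p = 0.742, 0.959 and 0.87). Of 18 astrocyte markers 0 rose and 2 fell (2 adjusted over the list alone), and 10 of the 18 had a control level above the median of all probe sets. The list was lower by camera (median -0.16, adjusted p = 0.00727), but not with an estimated correlation (adjusted p = 0.111) or with array brightness as a covariate (adjusted p = 0.0659). They were the glutamine synthetase gene Glul (3.15-fold lower, adjusted p = 0.00301, call lost in 5 of 23 other settings) and the vimentin gene Vim (1.95-fold lower, adjusted p = 0.0239, call lost in 13 of 23 other settings). Neither passed with no scaling (log2 fold changes -0.993 and -0.484), array medians subtracted (-1.12 and -0.607) or the trimmed mean (-1.50 and -0.971). Markers of fibroblasts and vessels did not pass (24 measured, camera adjusted p = 0.0528), although they were lower in 8 of 26 other settings, among them no scaling (adjusted p = 0.0252), array medians subtracted (0.0255), the trimmed mean (0.0166) and the omission of control culture 2 (adjusted p = 0.0383) or IFN-gamma culture 1 (adjusted p = 0.0281). In that list Col1a1 had a log2 fold change of 0.00 by its brightest probe set (adjusted p = 1), and another probe set fell by 1.20 (adjusted p = 0.0239). Oligodendrocyte lineage markers (14 measured, adjusted p = 0.331), neuron markers (29, 0.432) and lymphocyte markers (16, 0.816; median 0.03, mean -0.02) did not pass either, with 0 genes past the threshold and 0 adjusted over the list alone in these 3 lists and in the fibroblast list. Of the marker lists that did not pass by camera, only that of fibroblasts and vessels passed by fry (fry adjusted p = 0.0148). Mbp had a log2 fold change of 0.17 (adjusted p = 0.957). Fcgr3a and Gfap, on the fixed set, were not analysed here because no tested probe set carried either symbol alone.

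The 3 arrays of IFN-gamma culture 1 allowed the spread between arrays of the same culture to be set beside the spread between cultures. The median SD over probe sets was 0.308 between the 3 technical arrays and 0.289, 0.25 and 0.309 between the 3 IFN-gamma cultures when array 1a, 1b or 1c stood for culture 1. The spread between IFN-gamma cultures was thus of the same size as that between repeat arrays of a single culture. Arrays 1a, 1b and 1c also differed in brightness before normalisation, with median signals of 11.6, 23.7 and 11.1, against 17.2 and 20.9 in cultures 2 and 3. What brightness added to either spread was not tested, so the variation between cultures cannot be taken as negligible. Between the 5 control cultures it was 0.4, and between groups of 3 of them it ran from 0.307 to 0.391. Across probe sets, which are not independent replicates, the correlation was 0.852 to 0.886 between technical arrays, 0.849 to 0.914 between culture 1 arrays and cultures 2 and 3, and 0.778 to 0.884 between controls. These are descriptions without a test.

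Of the 51 named genes past the threshold all kept their direction in each of the settings in which they were tested, 27 kept their call in at least 20 of them and 9 in every one. With no scaling 34 of the 51 calls were lost, among them the call of every gene of the 51 that was lower with IFN-gamma. Omission of IFN-gamma culture 1, 2 or 3 lost 16, 15 and 18 and lowered the counts to 47 higher and 23 lower, 51 and 25, and 47 and 21. Leaving out control culture 1, 2, 3, 5 or 6 lost 4, 12, 4, 8 and 11 of the 51.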

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

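The spread of the 5 control cultures was examined for 139 values, and 7 of them held a culture far from the other 4, where chance gives about 1 in 20. The 7 are therefore about as many as chance alone would give. No biological explanation was tested for these values.

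In control culture 3, the dimmest array, the cyclin gene Ccng1 lay at 7.51 on the log2(signal + 16) scale against 8.60 to 9.04 in the other controls. In the same culture Pgam1, a glycolytic enzyme gene, lay at 7.35 against 8.21 to 8.45, and C3 lay at 7.68 against 8.39 to 8.68. In control culture 1 Sod2, the mitochondrial superoxide dismutase gene, lay at 9.21 against 6.32 to 6.67, the widest gap of the 7 in log2 units. The array control for the 3' end of beta-actin was lower in that culture, at 10.7 against 11.1 to 11.3. In control culture 2 the ribosomal gene Rpl27a lay at 9.97 against 10.3 to 10.5. Cd63 lay at 10.4 in control culture 1 and at 10.7 in the other 4, where quantile normalisation gave it values equal to 2 decimals. Of these only Cd63 was past the threshold for a change with IFN-gamma, and its 3 IFN-gamma cultures lay below all 5 controls.

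The array control probe sets, which were left out of the main tests, also held a difference between the groups. Fitted beside all other probe sets with limma, the GAPDH control for the 5' end was higher with IFN-gamma by 1.07 on the log2 scale (adjusted p = 0.016) and the one for the 3' end by 0.997 (adjusted p = 0.0413). The middle GAPDH control and the beta-actin controls for the middle and the 3' end had log2 fold changes of 0.943, 0.662 and 0.595 and did not pass (adjusted p = 0.109, 0.142 and 0.193). The ratio of the 3' to the 5' GAPDH signal was 1.64 ± 0.191 in the controls (SD, n = 5) and 1.45 ± 0.142 with IFN-gamma (SD, n = 3; exact permutation p = 0.214, adjusted p = 0.428).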

How the results depend on the processing

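The settings with no scaling between arrays, with scaling to a trimmed mean and with brightness as a covariate were chosen after the values were seen. All 134 probe sets past the threshold kept their direction in every setting that tested them, and 127 of 127 and 133 of 133 did under the filters on dim probe sets. The main counts were 81 higher and 53 lower. With all 10 arrays and culture as a random block the higher count was 124. With no scaling they were 38 and 1, with array medians subtracted the lower count was 27, with an offset of 1 they were 42 and 25, and with the trimmed mean scaled to 500 they were 42 and 24. The median log2 fold change of all probe sets was -0.02 in the main setting, 0.10 with no scaling and -0.15 with the trimmed mean, so directions under these are relative to those shifts. At an adjusted p under 0.01 the counts were 46 and 21, by absence of overlap alone 374 and 297, and counted as genes 42 and 33, as the rules themselves imply. Leaving out each culture in turn gave 47 to 105 higher and 21 to 48 lower, with the fewest where an IFN-gamma culture was left out and fewer samples remained.

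Same-numbered cultures of the groups did not deviate together (correlations of deviations -0.0266, 0.00383 and -0.0146). No IFN-gamma culture correlated best with the control of its own number, so the values gave no sign of pairing. They cannot exclude a shared brain or day, because repeat arrays of a single culture differed as much as the IFN-gamma cultures did. A fit with the replicate block called 17 higher and 5 lower, and 38 of the 51 named genes did not pass in it; only numbers 1, 2 and 3 occur in both groups, so only those cultures inform it. Pathway lists higher and lower by camera were 8 and 6. The count of lower lists was 3 with array medians subtracted and 2 with the trimmed mean, and with an estimated correlation the counts were 4 and 2. The estimated correlation was -0.0259 for glycolysis and -0.00683 for the cell cycle, below the preset 0.01, yet both calls were lost. Correlation among the members of these lists therefore does not account for the losses, and the 2 forms of camera differ in more than that value. The MHC class I, MHC class II, immunoproteasome, interferon GTPase, and protease and matrix lists held in all 26 settings. Lists past camera in the main setting also passed by fry, except oxidative phosphorylation and ribosomal proteins (fry adjusted p = 0.166 and 0.112). Complement, Fc receptors and adhesion, arginine and tryptophan, and fibroblast and vessel markers passed by fry alone. The ribosomal list turned, with medians of 0.376 with no scaling, 0.254 with array medians subtracted and -0.0265 (camera direction up) with the trimmed mean. Single probe sets of the opposite sign were -0.083 for RT1-Bb, -0.0862 for Cnn3, 0.194 for Igf1, 0.0821 for Fn1 and -0.0995 for Psme1. Except where a rule or sample number explains a count, the cause was not tested. Genes near the floor of 4 limit what the arrays can show. The ratio of the spread between IFN-gamma cultures to that between technical arrays was 0.918, a mean with array 1a, 1b or 1c standing for culture 1. The SD of 0.0974 is that between these 3 choices of array and not a sampling error between cultures. In the other settings run the mean ratio moved by less than that SD.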

Other observations

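Genes outside the lists and the naming rule also changed; those named here were chosen after their values were seen. Higher with IFN-gamma were Taldo1, an enzyme of the pentose phosphate pathway (log2 fold change 1.79, adjusted p = 0.0125), Plek, a substrate of protein kinase C (1.67, adjusted p = 0.0152), and the lysyl-tRNA synthetase gene Kars1 (1.54, adjusted p = 0.021). The mitochondrial translocator gene Tspo, used as a marker of microglial activation in brain imaging, was higher by 1.42 (adjusted p = 0.0224) and the ectoenzyme gene Bst1 by 1.48 (adjusted p = 0.026). Lower were the tetraspanin gene Cd81 (log2 fold change -1.52, adjusted p = 0.0059), the growth factor receptor gene Fgfr1 (-1.35, adjusted p = 0.021), the lysosomal sulfatase gene Arsb (-1.07, adjusted p = 0.028) and Cd4 (-1.02, adjusted p = 0.00792). The largest increase of a probe set with no listed gene was 3.37 (adjusted p = 1.04e-05), from a control level of 4.20, and 2 probe sets shared by several class I genes rose by 3.01 (adjusted p = 0.00342) and 1.93 (adjusted p = 0.00423).

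Both tests of the astrocyte genes and the tests that use the unscaled table, the trimmed mean or the brightness covariate were chosen only after results were seen. Chance in how the cultures were grouped was tested as the source of the count of changed probe sets. Of the 56 splits of the 8 cultures into 3 and 5, only the real one gave as many as 134 probe sets past the threshold. The highest other split gave 2. That is the smallest share the design allows (exact permutation p = 0.018), which makes chance unlikely but does not exclude it. The other splits mix the 2 groups on at least 1 side, which widens the spread there and lowers their counts. Nor can the splits part IFN-gamma from anything else that a group shared.

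The genes of the constitutive proteasome and of oxidative phosphorylation had a median log2 fold change of 0.393 together. Without control culture 3, the dimmest array, it was 0.364, which argues against that array as the source. With array brightness as a covariate, a setting chosen after results were seen, it was 0.233. That lay between the values set for and against brightness before that test was run. An effect of brightness and an effect of IFN-gamma therefore cannot be told apart for these lists. Both list calls were also lost with an estimated correlation.

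The 5 lysosomal genes past the threshold (Ctsd, Ctsl, Lamp1, Cd63 and Ctsb) had a median log2 fold change of -1.25. Compression of bright signals is a candidate explanation. After normalisation 49 other probe sets as bright in the controls had a median of -0.247, so equally bright probe sets did not share the fall. Quantile normalisation gives every array the same distribution and would remove a general compression. These values therefore cannot decide whether the deposited signals were compressed. With no scaling between arrays the median of the 5 was -0.542 and with the trimmed mean -1.01, so a part played by the normalisation cannot be told apart from an effect of IFN-gamma on the size of the fall. All 5 stayed below 0 under each scaling, and Ctsd and Ctsl stayed at or below -1.93. With no scaling, however, neither Ctsd nor Ctsl passed (adjusted p = 0.421 and 0.392).

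Glul and Vim, which astrocytes express strongly, had log2 fold changes of -1.66 and -0.96, a median of -1.31. With no scaling they were -0.993 and -0.484 (median -0.739), with array medians subtracted -1.12 and -0.607, and with the trimmed mean -1.50 and -0.971 (median -1.24), and neither passed in any of these. As for the lysosomal genes, a part played by the normalisation cannot be told apart from an effect of IFN-gamma on the size of the fall. Fewer astrocytes in the IFN-gamma cultures might also lower both. The other 8 astrocyte markers with a control level above the median of all probe sets (4.97) had a median log2 fold change of -0.285, and the standard error of their mean between cultures was 0.132. Their levels ran from 5.10 to 6.17, where a signal of 0 is 4. Markers of neurons and lymphocytes chosen by the same level reached 6.38 and 6.48, with median log2 fold changes of -0.205 and -0.177. The signal of the 8 may therefore be background that would not fall with the share of astrocytes, so fewer astrocytes and a response of the microglia to IFN-gamma cannot be told apart.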
